A study of Homo sapiens with 4 samples.

How the data were processed

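RNA was sequenced from 4 cultures of MCF-7 Tam1 cells, a derivative of the estrogen receptor-positive breast cancer line MCF-7 that was kept in 1 µM 4-hydroxytamoxifen, the active metabolite of tamoxifen, to maintain its resistance to the drug. Per the labels' protocols, the medium held 4.5 g/L glucose, 1 mM pyruvate, 10 µg/mL insulin and 10% serum, the siRNAs were delivered with a lipid transfection reagent, and stranded mRNA libraries were prepared from total RNA. Of the 4 libraries, 2 came from cells given a scrambled control siRNA and 2 from cells given an siRNA against NSUN7. The labels call the libraries of a group biological replicates without saying whether they came from separate transfections, so the p-values measure the spread between these libraries. The siRNA sequences, the dose and the time between transfection and harvest are not given in the sources used here.

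The submitters' processing notes name Trimmomatic, Salmon, FastQC and MultiQC and the genome build GRCh38.p13, without versions or options. The deposited files hold, per the file headers, an estimated read count and a TPM value for each transcript, next to its length and effective length. The estimated counts deposited by the authors are reads assigned to transcripts by the quantifier, are not whole numbers and are not normalized. The deposited TPM values are scaled by effective transcript length and have the same sum in each library. Because reads that match several transcripts are divided among them by a model, the division between transcripts of a gene, and between near-identical genes, is less certain than the sum over a gene.

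The estimated counts of all transcripts of a gene were summed and rounded to whole numbers. The totals were 44004484 and 46338694 reads in the control siRNA libraries and 49993818 and 45702852 in the NSUN7 siRNA libraries. At these depths a count of 0 allows up to 3 reads, and intervals of fold changes cover counting error and the spread between libraries only. The files list 62269 genes, of which 31654 had at least 1 read. The filter filterByExpr of edgeR, with its minimum count of 10 and minimum total of 15, left 17838 genes for testing, of which 13501 code for protein. Libraries were scaled with TMM factors of 0.998, 1.02, 0.966 and 1.02 for control siRNA 1, control siRNA 2, NSUN7 siRNA 1 and NSUN7 siRNA 2. The groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, without covariates, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom, 5.64 prior degrees of freedom and a common biological coefficient of variation of 0.136. Log2 fold changes are NSUN7 siRNA over control siRNA. Standard errors were derived from the fold change and its F statistic, and intervals are 95% intervals. CPM values are TMM-scaled. In simulated counts for the same comparison and 17838 genes, the test recovered 52% of 50 genes changed 1.5-fold, 94% of 50 changed 2-fold, and 100% of 50 changed 3-fold and of 50 changed 4-fold. The changed genes were drawn from those with a mean of at least 4 CPM, so recovery of genes with fewer reads was not measured. Among its 195 calls, 22 (11.3%) were genes simulated without a change, which is more than the nominal share.

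The comparison, the genes to be named and 34 gene lists were fixed before the data were examined. Named were NSUN7, the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups, up to 4 members of smallest p in each list, and 12 further genes whatever their values. Lists were tested with camera of limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists, and again with an estimated correlation. The rotation test fry tested whether the members of a list moved on balance one way, or in either direction. For each list the calls are given over all genes tested and with p-values adjusted over the list alone.

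The alternatives fixed in advance were size factors of DESeq2 in place of TMM, no filter, a filter of at least 50 reads in at least 2 libraries, the Wald test of DESeq2 1.42.0, limma-trend on log2(TPM + 1) and on log2(TPM + 0.1), counts rebuilt from TPM and mean effective length, protein-coding genes only, the replicate number as a block, and leaving out each library in turn. Robust dispersions, the newer quasi-likelihood of edgeR, NSUN7 counted from its protein-coding transcripts, and gene sets without certain 3′ UTR heptamers were added after the data had been seen.

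The search for short sequences was also chosen after the fold changes had been seen. For each gene, the most abundant protein-coding transcript with a 3′ UTR of at least 50 bases was taken from GENCODE 29, which is on the same primary assembly, and all coordinates are from this annotation. Among protein-coding genes with a mean log2 CPM of at least 2, 10386 of 10515 (98.8%) had such a 3′ UTR. Their log2 fold changes, limited to 2 in either direction, were regressed on 3′ UTR length and GC content, and the mean residual of genes with each of 16249 heptamers present in at least 30 genes was compared with that of the other genes. Intervals of mean residuals came from 2000 bootstrap samples of genes, so they carry no spread between libraries. A scan of shuffled fold changes gave the range expected without any relation. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for these steps and for the plots. The reads of the 2 libraries of a group differed by more than sampling noise, with a chi-square of 23.0 per degree of freedom in the control siRNA libraries and 43.6 in the NSUN7 siRNA libraries, over genes with at least 100 reads in the 2 libraries together. This cannot show that the libraries came from separate transfections. Each library was counted as its own replicate, as the labels call them biological replicates.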

Results

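Gene expression was measured by mRNA sequencing in tamoxifen-resistant MCF-7 Tam1 breast cancer cells given a control siRNA (n = 2 libraries) or an siRNA against NSUN7 (n = 2 libraries). NSUN7 belongs to the NOL1/NOP2/SUN family, whose members write 5-methylcytosine in RNA, and the study describes its expression as higher in the resistant cells. The comparison asks which transcripts differ when these cells receive the NSUN7 siRNA. Each library held 44004484 to 49993818 assigned reads, and 17201 to 18317 genes had at least 10 reads. NSUN7 siRNA library 2 stood apart from the other libraries: 4.24% of its reads lay on retained-intron transcripts, against 3.09% to 3.28% elsewhere, and 10.6% came from the mitochondrial genome, against 6.59% and 8.03% in the controls and 8.74% in NSUN7 siRNA library 1.

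The targeted gene was read at low levels in every library. Summed over its transcripts, NSUN7 (ENSG00000179299.17, plus strand of chromosome 4 from 40749897 to 40809985, GRCh38) had 4.90 and 5.08 CPM in the control siRNA libraries and 2.53 and 3.30 CPM in the NSUN7 siRNA libraries. The mean was 41.5% lower, with a log2 fold change of −0.77 ± 0.22 (SE, 95% interval −1.27 to −0.27). In edgeR's quasi-likelihood test this gave a Benjamini-Hochberg adjusted p of 0.0942, so the decrease did not pass the threshold over all genes. The difference lay in the reads assigned to retained-intron transcripts, which summed to 2.70 ± 0.37 CPM (SD, n = 2) in the controls and 0.566 ± 0.77 CPM (SD, n = 2) in the NSUN7 siRNA libraries. Most of these were on NSUN7-206, with 2.65 ± 0.30 CPM (SD, n = 2) in the controls and 0.553 ± 0.78 CPM (SD, n = 2) in the NSUN7 siRNA libraries. The protein-coding NSUN7 transcripts had 2.14 ± 0.26 CPM (SD, n = 2) with control siRNA and 2.24 ± 0.21 CPM (SD, n = 2) with NSUN7 siRNA. Their log2 fold change was 0.06 (95% interval −0.51 to 0.64, edgeR adjusted p = 0.92), so no decrease of the coding transcripts was detectable at this depth. The interval reaches down to a fall of 0.51 on the log2 scale. It carries no error from the division of reads between transcripts, so a larger fall is not excluded. Because reads shared by these transcripts are divided by a model, the split is less certain than the sum. APBB2, the neighbouring gene, had a log2 fold change of −0.26 ± 0.10 (SE) and did not pass (edgeR adjusted p = 0.191).

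**Figure D1:**
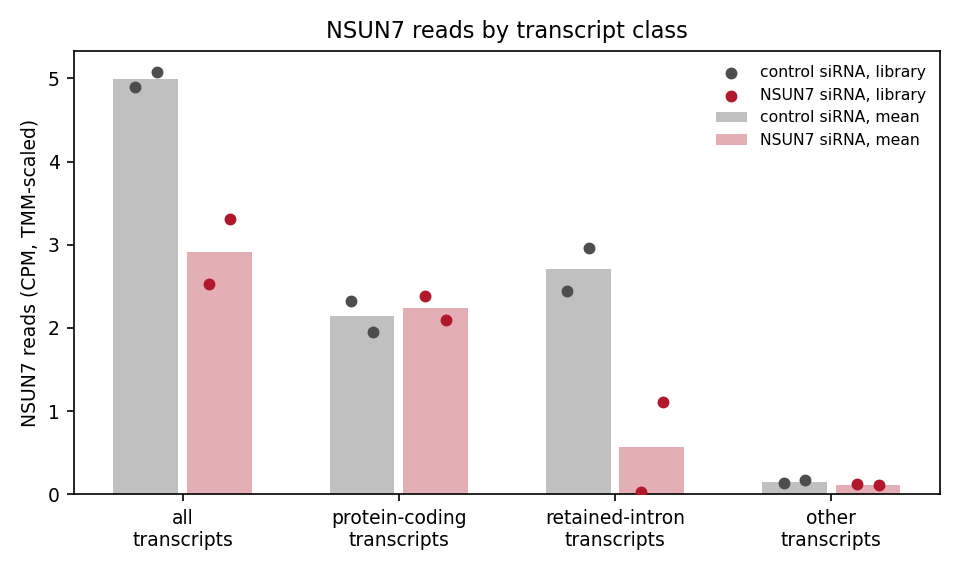
NSUN7 reads per library, in TMM-scaled CPM, for all transcripts of the gene and for its protein-coding, retained-intron and other transcripts, with points for the libraries (n = 2 per group) and bars for their means. The groups lie apart for all transcripts (4.90 and 5.08 against 2.53 and 3.30 CPM) and for retained-intron transcripts, while the protein-coding transcripts overlap.

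Of 17838 genes tested, 756 passed the threshold of 0.05, of which 443 rose and 313 fell in the NSUN7 siRNA libraries. They include 417 protein-coding genes that rose and 284 that fell. A change of at least 1.5-fold was seen for 383 of the genes that rose and 215 of those that fell, and of at least 2-fold for 140 and 71. Among protein-coding genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups, the largest rise was in CHPF, which encodes a chondroitin polymerizing factor (ENSG00000123989.15, minus strand of chromosome 2 from 219538947 to 219543787). It went from 34.3 ± 7.23 CPM (SD, n = 2) to 211 ± 36.0 CPM (SD, n = 2), a log2 fold change of 2.62 ± 0.18 (SE, edgeR adjusted p = 0.00227). HIPK3, a homeodomain-interacting protein kinase gene (ENSG00000110422.12, plus strand of chromosome 11 from 33256672 to 33357023), rose from 15.3 ± 2.14 to 78.2 ± 2.64 CPM (SD, n = 2 each), a log2 fold change of 2.35 ± 0.12 (SE, edgeR adjusted p = 0.00186). EMP2, which encodes an epithelial membrane protein, rose by 1.98 ± 0.14 on the log2 scale, and YWHAH, a 14-3-3 protein gene, rose by 1.82 ± 0.13 (SE, edgeR adjusted p = 0.00227 for both). ATP6AP1, an accessory subunit of the vacuolar proton pump, went from 83.8 ± 9.68 to 294 ± 44.3 CPM (SD, n = 2 each). IQSEC1, an exchange factor for ARF GTPases, went from 37.1 ± 3.79 to 128 ± 3.32 CPM (SD, n = 2 each). The metalloproteinase inhibitor gene TIMP3 rose by 1.95 ± 0.31 and the fibrillar collagen gene COL27A1 by 1.80 ± 0.17 (SE, edgeR adjusted p = 0.0178 and 0.00386). Both calls were lost with limma-trend on log2(TPM + 1) (limma adjusted p = 0.0753 and 0.063) and on log2(TPM + 0.1) (limma adjusted p = 0.0557 and 0.0706), and that of TIMP3 with robust dispersions (edgeR adjusted p = 0.0894). NUDT15, a nucleotide hydrolase gene, STEAP3, which encodes an endosomal ferrireductase, TOP1MT, the mitochondrial topoisomerase gene, and the kinesin gene KIF12 rose by 1.79, 1.77, 1.76 and 1.75 on the log2 scale (SE 0.15, 0.13, 0.18 and 0.20).

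The largest fall among the named genes was in FZD6, a Frizzled receptor for WNT ligands (ENSG00000164930.12, plus strand of chromosome 8 from 103298433 to 103332866). It went from 89.8 ± 3.53 to 28.1 ± 0.83 CPM (SD, n = 2 each), a log2 fold change of −1.68 ± 0.10 (SE, edgeR adjusted p = 0.00197). LAMTOR5, a subunit of the Ragulator complex on lysosomes, fell by 1.36 ± 0.12 and AJUBA, a LIM-domain protein that takes part in Hippo signalling, fell by 1.29 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 0.00238 for both). ABCB10, a transporter of the mitochondrial inner membrane, went from 47.2 ± 0.98 to 19.9 ± 1.37 CPM (SD, n = 2 each). TWSG1, which encodes an extracellular modulator of BMP signalling, went from 60.5 ± 0.52 to 25.6 ± 1.23 CPM (SD, n = 2 each). The tetraspanin gene TSPAN6 and the formin gene DIAPH3 both fell by 1.23 on the log2 scale (SE 0.14 and 0.12). The chloride/proton exchanger gene CLCN4 fell by 1.42 ± 0.25, the cytokine gene TNFSF15 by 1.33 ± 0.18, the adhesion protein gene FLRT3 by 1.27 ± 0.22 and CAB39L by 1.25 ± 0.26 (SE, edgeR adjusted p = 0.0237, 0.0106, 0.0229 and 0.0449). The fall of SERF1B (−1.62 ± 0.14, SE) is uncertain, because its near-identical copy SERF1A, named after its values had been seen, went the other way, from 0.0228 and 0.722 CPM to 7.77 and 6.03 CPM. The sum of both genes was 19.4 ± 1.11 CPM with control siRNA and 13.1 ± 1.08 CPM with NSUN7 siRNA (SD, n = 2 each). Of the 24 genes with the largest changes, 23 kept their call when any 1 library was left out, and CAB39L lost it without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0897). With limma-trend on log2(TPM + 1), 6 of the 24 lost their call, which were CAB39L, CLCN4, FLRT3 and TNFSF15 (limma adjusted p = 0.0822, 0.0632, 0.104 and 0.0629) beside TIMP3 and COL27A1. On log2(TPM + 0.1) the same genes except TNFSF15 lost it (limma adjusted p = 0.063, 0.0675 and 0.0887 for CAB39L, CLCN4 and FLRT3). CAB39L, CLCN4 and FLRT3 also lost it without a filter (edgeR adjusted p = 0.105, 0.0619 and 0.0501), and CAB39L with the 50-read filter and with robust dispersions (edgeR adjusted p = 0.0515 and 0.101).

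**Figure D2:**
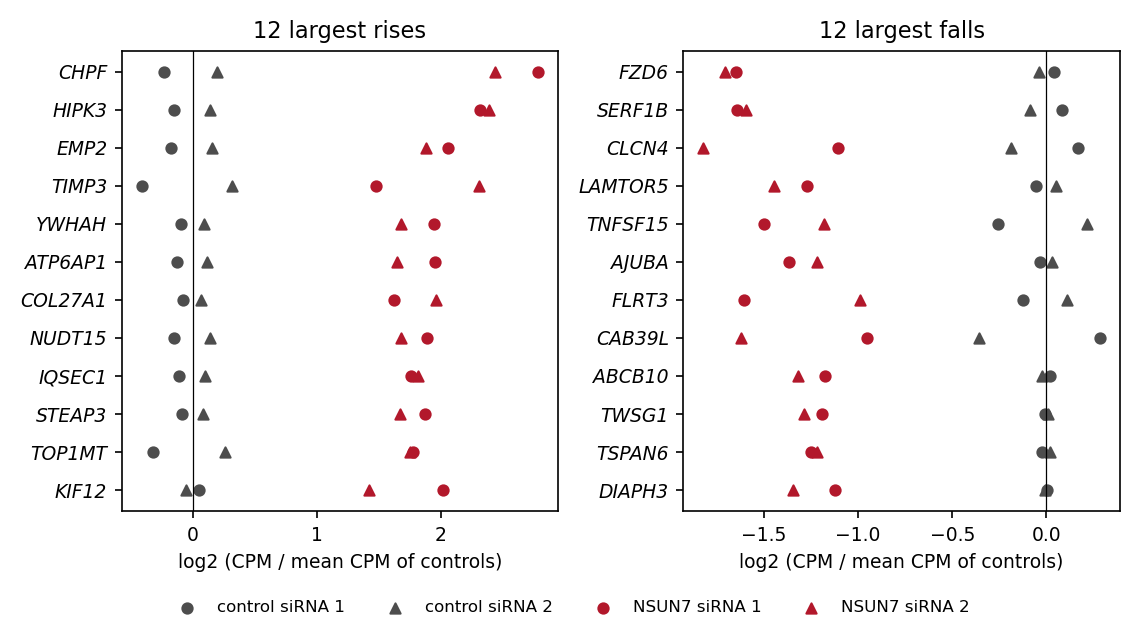
Log2 ratio of the CPM of each library to the mean CPM of the control siRNA libraries, for the 12 protein-coding genes with the largest rise and the 12 with the largest fall, with 1 point per library. All points of the NSUN7 siRNA libraries lie beyond those of the control siRNA libraries, which was a condition for naming these genes, and TIMP3, CLCN4 and CAB39L show the widest spread between replicates.

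The number of calls depended on single libraries and on the test. It was 380 without control siRNA library 1, 518 without control siRNA library 2, 1761 without NSUN7 siRNA library 1 and 877 without NSUN7 siRNA library 2, and it was 280 without a filter, 1580 with DESeq2, and 272 and 451 with limma-trend on log2(TPM + 1) and log2(TPM + 0.1). Genes that rose were 58.6% of the calls, but 46.3% and 41.9% with limma-trend on log2(TPM + 1) and log2(TPM + 0.1). Of the 71 called genes named here, 40 lost their call with limma-trend on log2(TPM + 1), 29 on log2(TPM + 0.1), 38 without a filter, 17 with counts rebuilt from TPM and 3 with robust dispersions. Apart from the gene set without heptamers, under which single genes were not followed, no alternative ended the calls of 26, which are 18 of the 24 largest changes and RET, TFAP2C, MAPK3, FGFR4, PRC1, SLC7A11, TGFB1 and TNRC6A. For 9124 genes tested (51.1%) the libraries of the groups did not overlap, where chance gives 33.3%.

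Genes that rose and genes that fell differed from other genes in short sequences of their 3′ UTRs, in a search made after the fold changes had been seen. GCAGTAC, TCAAGAT and CAAGATA were chosen for the most extreme z in a scan of these same fold changes. Their enrichment among the calls was thus largely given in advance. The odds ratios and p-values below describe it without testing it, and are not adjusted for 3′ UTR length. The heptamer GCAGTAC was present in the 3′ UTR of 124 of 414 searched genes that rose (29.9%) and of 396 of 12547 genes that were not called (3.16%), an odds ratio of 13.1 (95% interval 10.3 to 16.6, two-sided Fisher's exact test, p = 3.65e-76). Genes that fell carried it in 6 of 280 cases (2.14%). With the coding sequence counted too, it was present in 251 of 414 genes that rose (60.6%) and in 13.9% of genes not called. TCAAGAT or CAAGATA was present in 113 of 280 searched genes that fell (40.4%) and in 1606 of 12547 genes not called (12.8%), an odds ratio of 4.61 (95% interval 3.58 to 5.92, two-sided Fisher's exact test, p = 7.74e-30). Genes that rose carried TCAAGAT or CAAGATA in 56 of 414 cases (13.5%). With the coding sequence counted too, these were present in 173 of 280 genes that fell (61.8%) and in 30.1% of genes not called. Among the 12 largest rises, GCAGTAC lay in the 3′ UTR of 7, namely CHPF, HIPK3, EMP2, YWHAH, NUDT15, STEAP3 and TOP1MT, and in the coding sequence of TIMP3 and COL27A1. ATP6AP1, IQSEC1 and KIF12 had it in neither. EMP2 and YWHAH rose although their 3′ UTRs also hold TCAAGAT or CAAGATA, which COL27A1 and TOP1MT hold in the coding sequence. Among the 12 largest falls, TCAAGAT or CAAGATA lay in the 3′ UTR of 8, namely FZD6, SERF1B, LAMTOR5, FLRT3, ABCB10, TWSG1, TSPAN6 and DIAPH3, while CLCN4, TNFSF15, AJUBA and CAB39L had neither heptamer in the 3′ UTR or the coding sequence. DIAPH3 fell although its coding sequence holds GCAGTAC. Without the genes that carry any of these heptamers in the 3′ UTR, 347 genes were called, of which 222 rose and 125 fell. All 347 were among the 756, of which 268 were left out with their genes, so other calls were also lost in this fit.

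**Figure D3:**
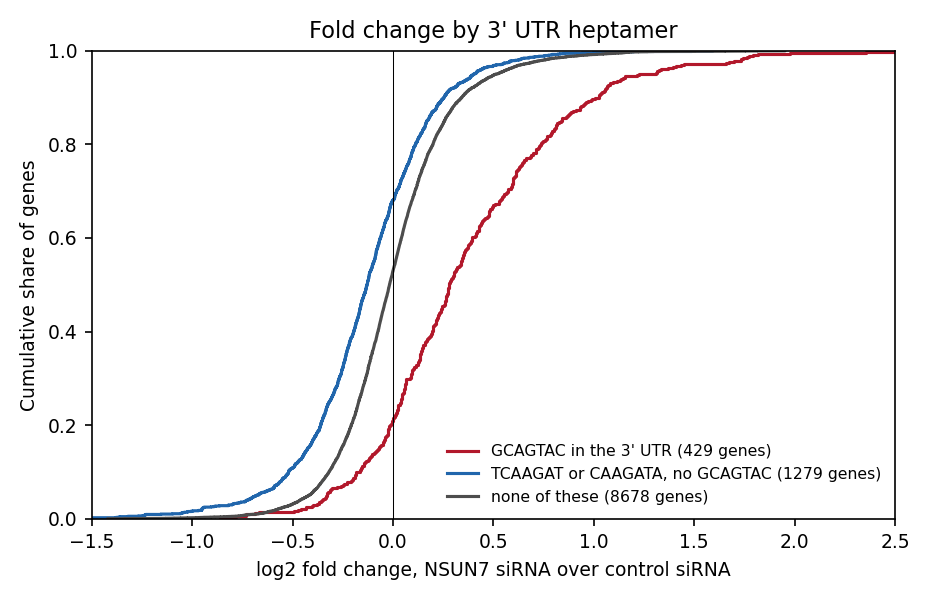
Cumulative share of protein-coding genes (y axis) against their log2 fold change, NSUN7 siRNA over control siRNA (x axis), for genes with GCAGTAC in the 3′ UTR (429 genes), genes with TCAAGAT or CAAGATA and no GCAGTAC (1279 genes) and genes with none of these (8678 genes). The curve of GCAGTAC genes lies to the right of the others, and the curve of TCAAGAT or CAAGATA genes lies to the left.

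Among 15 enzymes and readers of 5-methylcytosine in RNA, only TET3 was called: the gene of this methylcytosine dioxygenase, which holds TCAAGAT or CAAGATA in the coding sequence, fell by 0.47 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 0.0449). With p-values adjusted over the list alone, 2 members rose and 2 fell. TET1 (−0.89 ± 0.22), the m5C reader ALYREF (0.46 ± 0.11) and the mitochondrial methyltransferase NSUN3 (0.53 ± 0.13) did not pass over all genes. The list as a whole did not stand apart (camera adjusted p = 0.859). In the RNA interference machinery, 2 of 13 members rose and 1 fell, against 3 and 2 adjusted over the list alone. TNRC6A and TNRC6C, the GW182 proteins that bind Argonaute, rose by 1.18 ± 0.12 and 1.26 ± 0.18, and AGO1 fell by 0.44 ± 0.09 (SE, edgeR adjusted p = 0.00452, 0.0128 and 0.0435). GCAGTAC lies in the coding sequence of TNRC6A and TNRC6C, while AGO1 carries TCAAGAT or CAAGATA in the 3′ UTR and both these and GCAGTAC in the coding sequence. This list did not pass either (camera adjusted p = 0.859). The calls of TET3 and AGO1 were lost without control siRNA library 1 (edgeR adjusted p = 0.249 and 0.196) and without control siRNA library 2 (edgeR adjusted p = 0.151 and 0.17).

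Of 42 genes known to rise with estradiol in MCF-7 cells, 6 rose and none fell over all genes, against 8 and 5 adjusted over the list alone. The receptor tyrosine kinase gene RET went from 162 ± 1.10 to 284 ± 2.17 CPM (SD, n = 2 each). MYB, ADCY9 and OLFM1 rose by 1.17 ± 0.22, 0.96 ± 0.12 and 0.81 ± 0.14 on the log2 scale (SE, edgeR adjusted p = 0.0284, 0.00761 and 0.0219). ADCY9, OLFM1 and MYB carry GCAGTAC in their coding sequences, and RET and ADCY9 carry TCAAGAT or CAAGATA there. The members did not move together (camera adjusted p = 0.833). The receptor gene ESR1 had 174 ± 11.7 and 232 ± 26.0 CPM (SD, n = 2 each), a log2 fold change of 0.42 that did not pass (edgeR adjusted p = 0.1). TFF1 (0.46 ± 0.20), CCND1 (−0.26 ± 0.12), PGR (−0.99 ± 0.90) and GREB1 (−0.72 ± 0.56) did not pass either, the last 2 at under 4 CPM in every library. Their signs turned without control siRNA library 2, to 0.04 for PGR and 0.27 for GREB1. Among 22 luminal identity genes, TFAP2C, the AP-2 gamma transcription factor gene, and the mucin gene MUC1 rose by 0.77 ± 0.11 and 0.90 ± 0.18 (SE, edgeR adjusted p = 0.0123 and 0.0383), with 6 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.258). TFAP2C carries GCAGTAC in the 3′ UTR and MUC1 in the coding sequence. MUC1 lost its call without NSUN7 siRNA library 1 (edgeR adjusted p = 0.0584) and without control siRNA library 2 (edgeR adjusted p = 0.0572), and MYB without control siRNA library 1 (edgeR adjusted p = 0.122).

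In the list of 31 tested receptors, kinases and adaptors linked to tamoxifen resistance, 2 rose and 1 fell, against 5 and 3 adjusted over the list alone. MAPK3, the gene of the kinase ERK1, went from 49.5 ± 4.24 to 138 ± 11.5 CPM (SD, n = 2 each), a log2 fold change of 1.48 ± 0.11 (SE, edgeR adjusted p = 0.00238). FGFR4 rose by 0.80 ± 0.11, and IGF1R, the insulin-like growth factor receptor gene, fell by 0.51 ± 0.10 (SE, edgeR adjusted p = 0.0124 and 0.0404). MAPK3 and FGFR4 carry GCAGTAC in their coding sequences, and FGFR4 also TCAAGAT or CAAGATA. EGFR (0.62 ± 0.20), ERBB2 (0.14 ± 0.10), PIK3CA (−0.46 ± 0.11) and BCL2 (0.07 ± 0.46) did not pass, and the list did not stand apart (camera adjusted p = 0.833). The call of IGF1R was lost without control siRNA library 1 (edgeR adjusted p = 0.249) and without control siRNA library 2 (edgeR adjusted p = 0.0875). Among 18 tested genes of drug transport and metabolism, 2 rose and 2 fell, against 3 and 5 adjusted over the list alone (camera adjusted p = 0.859). CYP1A1, a target of the aryl hydrocarbon receptor, fell by 1.01 ± 0.20 and the glucuronosyltransferase gene UGT2B17 by 1.40 ± 0.27, while the efflux transporter gene ABCC4 and the sulfotransferase gene SULT2B1 rose by 0.56 ± 0.11 and 0.59 ± 0.12 (SE, edgeR adjusted p = 0.0339, 0.0326, 0.0326 and 0.0417). Without control siRNA library 1 all 4 calls were lost (edgeR adjusted p = 0.122, 0.0836, 0.278 and 0.302). UGT2B17 and ABCC4 were also lost without control siRNA library 2 (edgeR adjusted p = 0.196 and 0.0675), UGT2B17, SULT2B1 and CYP1A1 without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0589, 0.0589 and 0.0719), and CYP1A1 without NSUN7 siRNA library 1 (edgeR adjusted p = 0.0541). ABCC4 carries GCAGTAC in the 3′ UTR and the coding sequence and TCAAGAT or CAAGATA in the coding sequence. UGT2B17 has close relatives in its gene family, so its reads are uncertain. CCDC9B, named in advance, had 4, 4, 4 and 3 reads and was not tested.

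In signalling, YAP and TEAD targets fell as a list (camera adjusted p = 0.0439), with 13 of 19 tested members below 0 and a median log2 fold change of −0.36. With an estimated correlation the p was 0.271 (adjusted p = 0.999). AJUBA and MYOF, the latter a membrane repair protein gene with TCAAGAT or CAAGATA in its coding sequence, fell over all genes, and 1 member rose and 5 fell adjusted over the list alone. MYOF went from 636 ± 57.2 to 408 ± 17.0 CPM (SD, n = 2 each), and AMOTL2 (−0.43 ± 0.10) and WTIP (−0.69 ± 0.17) did not pass. The list did not pass without control siRNA library 1 (camera adjusted p = 0.252), without NSUN7 siRNA library 2 (camera adjusted p = 0.255) or with the 50-read filter (camera adjusted p = 0.0833), and MYOF lost its call without control siRNA library 2 (edgeR adjusted p = 0.138). The TGF-beta list moved in both directions, with 3 of 19 members rising and 1 falling, against 4 and 4 adjusted over the list alone (camera adjusted p = 0.995). The ligand TGFB1 (0.92 ± 0.12), the type I receptor TGFBR1 (0.83 ± 0.11) and the pseudoreceptor BAMBI (0.60 ± 0.12) rose, while the type II receptor TGFBR2 fell by 0.95 ± 0.19 (SE, edgeR adjusted p = 0.00909, 0.00911, 0.0315 and 0.0347). GCAGTAC lies in the coding sequence of TGFB1, and TCAAGAT or CAAGATA in the 3′ UTR of TGFBR2. BAMBI and TGFBR2 lost their calls without control siRNA library 1 (edgeR adjusted p = 0.167 and 0.0564) and without control siRNA library 2 (edgeR adjusted p = 0.0954 and 0.207), and TGFBR2 also without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0576). Of 17 NOTCH pathway genes, RBPJ, the DNA-binding partner of NOTCH, rose from 24.2 ± 1.07 to 50.4 ± 3.42 CPM (SD, n = 2 each), as the only member called over all genes or over the list alone (camera adjusted p = 0.859). Among 23 genes of RAS and MAPK output, the ERK phosphatase genes DUSP4 and DUSP5 rose by 0.77 ± 0.12 and 1.13 ± 0.24, and the ephrin receptor gene EPHA2 fell by 0.51 ± 0.10 (SE, edgeR adjusted p = 0.0168, 0.0449 and 0.0394), with 4 rising and 5 falling over the list alone (camera adjusted p = 0.859). In their coding sequences DUSP5 holds GCAGTAC and EPHA2 holds TCAAGAT or CAAGATA. DUSP4, DUSP5 and EPHA2 lost their calls without control siRNA library 2 (edgeR adjusted p = 0.0522, 0.229 and 0.203), DUSP5 and EPHA2 also without control siRNA library 1 (edgeR adjusted p = 0.251 and 0.143), and DUSP5 without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0685). Of 13 WNT targets tested, CD44 alone rose over all genes, by 0.62 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 0.0205), and 3 rose and 1 fell over the list alone (camera adjusted p = 0.859). Its call was lost without control siRNA library 1 (edgeR adjusted p = 0.128) and without control siRNA library 2 (edgeR adjusted p = 0.0875).

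Of 31 interferon-stimulated genes tested, a class that double-stranded RNA can raise, none rose and 2 fell over all genes and over the list alone (camera adjusted p = 0.722). These were OAS1 (−0.59 ± 0.12) and OAS3 (−0.45 ± 0.10), which encode oligoadenylate synthetases (SE, edgeR adjusted p = 0.0407 and 0.0474). Both calls were lost without control siRNA library 1 (edgeR adjusted p = 0.167 and 0.195) and without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0666 and 0.059), and that of OAS3 without control siRNA library 2 (edgeR adjusted p = 0.16). Of 15 tested NF-kB targets, BCL3 rose by 0.62 ± 0.12 (SE, edgeR adjusted p = 0.0308), and 1 rose and 1 fell over the list alone (camera adjusted p = 0.78). Its call was lost without control siRNA library 1 (edgeR adjusted p = 0.167) and without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0508). None of 15 antigen presentation genes was called by edgeR over all genes and 1 fell over the list alone (camera adjusted p = 0.995), ERAP1 having the smallest p (−0.44 ± 0.11).

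DNA repair genes fell as a list (camera adjusted p = 0.0439): 19 of 23 homologous recombination and Fanconi anaemia genes lay below 0, with a median log2 fold change of −0.13. With an estimated correlation the p was 0.0805 (adjusted p = 0.999). RBBP8, which encodes the end-resection factor CtIP, fell from 53.7 ± 0.70 to 36.6 ± 0.71 CPM and RAD54L from 34.4 ± 0.55 to 24.7 ± 1.29 CPM (SD, n = 2 each), and 4 members fell over the list alone. The list did not pass without control siRNA library 2 (camera adjusted p = 0.261), without NSUN7 siRNA library 1 (camera adjusted p = 0.163) or with the 50-read filter (camera adjusted p = 0.0833). The calls of RBBP8 and RAD54L were lost without control siRNA library 1 (edgeR adjusted p = 0.0767 and 0.191) and without control siRNA library 2 (edgeR adjusted p = 0.0761 and 0.218), and that of RAD54L without NSUN7 siRNA library 1 (edgeR adjusted p = 0.0512). In the G2/M and mitosis list, 29 of 37 genes lay below 0, but the 2 members called over all genes and over the list alone both rose. PRC1, a regulator of the central spindle that carries GCAGTAC in its 3′ UTR, went from 101 ± 1.51 to 274 ± 30.1 CPM (SD, n = 2 each), and the mitotic kinesin gene KIF20A rose by 0.62 ± 0.10 (SE, edgeR adjusted p = 0.0172). This list had a camera adjusted p of 0.0714, downward. Without the genes that hold the heptamers in the 3′ UTR the camera adjusted p was 0.0199. It was 0.134 with the 50-read filter and 0.999 with an estimated correlation, and fry gave an adjusted p of 0.678. The direction stayed downward whichever library was left out, but whether the list passed depended on that library. KIF20A lost its call without control siRNA library 1 (edgeR adjusted p = 0.111). None of 36 G1/S and replication genes was called by edgeR over all genes or over the list alone (camera adjusted p = 0.722). The direction of this list was downward without NSUN7 siRNA library 1 and upward without NSUN7 siRNA library 2. The S-phase genes CHAF1A (0.30 ± 0.11) and RRM1 (−0.28 ± 0.11) had among the smallest p. Of 28 p53 targets, TP53INP1 and GDF15 rose by 0.65 ± 0.11 and 0.62 ± 0.12 (SE, edgeR adjusted p = 0.0224 and 0.0367), with 2 rising and 1 falling over the list alone (camera adjusted p = 0.859), while CDKN1A (−0.36 ± 0.10) did not pass. Among 34 apoptosis regulators the effector caspase gene CASP6 fell by 0.66 ± 0.12 (SE, edgeR adjusted p = 0.0273), as the only member over all genes and over the list alone (camera adjusted p = 0.258). The direction of this list was downward whichever library was left out, but it passed only without NSUN7 siRNA library 1. CASP6 holds TCAAGAT or CAAGATA in its coding sequence. TP53INP1, GDF15 and CASP6 lost their calls without control siRNA library 1 (edgeR adjusted p = 0.127, 0.142 and 0.126), and TP53INP1 and CASP6 without control siRNA library 2 (edgeR adjusted p = 0.0522 and 0.107).

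In metabolism and stress responses, the cystine transporter gene SLC7A11, a target of both NRF2 and ATF4, fell from 51.3 ± 2.91 to 23.8 ± 1.28 CPM (SD, n = 2 each), a log2 fold change of −1.11 ± 0.10 (SE, edgeR adjusted p = 0.00341). It and the malic enzyme gene ME1 (−0.50 ± 0.10, edgeR adjusted p = 0.0327) were the 2 of 22 NRF2 targets that fell, over all genes and over the list alone, and none rose (camera adjusted p = 0.14). The direction of the NRF2 list was downward whichever library was left out, but it passed only without NSUN7 siRNA library 1. Of 31 genes of the integrated stress response and unfolded protein response, SLC7A11 fell and the chaperone gene HYOU1 rose by 0.49 ± 0.10 (SE, edgeR adjusted p = 0.0434), against 4 rising and 3 falling over the list alone (camera adjusted p = 0.797). Of 24 tested cholesterol synthesis genes, INSIG1, a sterol sensor of the endoplasmic reticulum, fell by 0.51 ± 0.10 (SE, edgeR adjusted p = 0.0415), as the only call over all genes and over the list alone (camera adjusted p = 0.14). HMGCR (−0.27 ± 0.10) and HMGCS1 (−0.33 ± 0.11) did not pass. Of 23 genes of fatty acid synthesis and lipid storage, ME1 and ACLY, the ATP-citrate lyase gene, fell, the latter by 0.49 ± 0.11 (SE, edgeR adjusted p = 0.0484), and 1 rose and 3 fell over the list alone (camera adjusted p = 0.722). ME1 and ACLY carry TCAAGAT or CAAGATA in their 3′ UTRs, and HYOU1 carries GCAGTAC. HYOU1, ME1, INSIG1 and ACLY lost their calls without control siRNA library 1 (edgeR adjusted p = 0.304, 0.0808, 0.211 and 0.154) and without control siRNA library 2 (edgeR adjusted p = 0.187, 0.155, 0.112 and 0.241). None of 18 heat shock genes (camera adjusted p = 0.743) and none of 30 genes of hypoxia and glycolysis (camera adjusted p = 0.926) was called by edgeR over all genes or over the list alone. In these lists HSP90AA1 (0.53 ± 0.14) and the glucose transporter gene SLC2A1 (−0.59 ± 0.14) had the smallest p.

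All 13 mitochondrially encoded mRNAs lay above 0, with a median log2 fold change of 0.40, and the list rose (camera adjusted p = 0.0048). With an estimated correlation the p was 0.259 (adjusted p = 0.999). No member passed edgeR's threshold over all genes or over the list alone. MT-ND1 had 3873 ± 729 and 5551 ± 463 CPM (SD, n = 2 each), a log2 fold change of 0.52 ± 0.17 (SE, edgeR adjusted p = 0.136). The mitochondrial share of reads was highest in NSUN7 siRNA library 2 (10.6%) and lowest in control siRNA library 2 (6.59%), and the list did not pass without the first (camera adjusted p = 0.0509) or the second (camera adjusted p = 0.129). None of 40 nuclear-encoded subunits of the respiratory chain was called by edgeR over all genes or over the list alone (camera adjusted p = 0.859). NDUFB10 (0.36 ± 0.10) and NDUFS2 (−0.33 ± 0.10) had the smallest p. The direction of the list was downward without NSUN7 siRNA library 1 and upward without NSUN7 siRNA library 2. Of 19 tested genes of PGC-1 alpha and its partners, the coactivator gene PPARGC1B rose by 0.82 ± 0.14 (SE, edgeR adjusted p = 0.0233), as the only call over all genes and over the list alone (camera adjusted p = 0.658), although its 3′ UTR holds TCAAGAT or CAAGATA, and PPARGC1A (0.59 ± 0.26) did not pass. None of 48 ribosomal protein genes was called over all genes or over the list alone (camera adjusted p = 0.859). The direction of this list turned with the library left out: it passed downward without NSUN7 siRNA library 1 (camera adjusted p = 0.0171) and upward without NSUN7 siRNA library 2 (camera adjusted p = 0.00303). Of 26 genes of ribosome biogenesis and MYC, POLR1A, the catalytic subunit of RNA polymerase I, rose by 0.85 ± 0.16 (SE, edgeR adjusted p = 0.0279), as the only call over all genes and over the list alone (camera adjusted p = 0.212), and MYC itself (0.58 ± 0.16) did not pass (edgeR adjusted p = 0.0929). POLR1A carries GCAGTAC in its coding sequence. Of 16 tested replication-dependent histone genes, 13 lay above 0 and none was called over all genes or over the list alone (camera adjusted p = 0.347). The histone list was upward without either control siRNA library or without NSUN7 siRNA library 2, but downward without NSUN7 siRNA library 1. PPARGC1B and POLR1A lost their calls without control siRNA library 1 (edgeR adjusted p = 0.114 and 0.0712), and POLR1A also without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0544).

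Of 11 tested basal and myoepithelial markers, CD44 rose, and 3 rose and 2 fell over the list alone (camera adjusted p = 0.868). Of 15 tested genes of mesenchymal transition, CD44 and the collagen gene COL6A1 (0.94 ± 0.16, SE, edgeR adjusted p = 0.0229) rose, over all genes and over the list alone (camera adjusted p = 0.859), and COL6A1 holds GCAGTAC in its coding sequence, while THBS1 (−0.49 ± 0.18) and CCN1 (−0.76 ± 0.30) did not pass. CD44 and COL6A1 lost their calls without control siRNA library 1 (edgeR adjusted p = 0.128 and 0.0714) and without control siRNA library 2 (edgeR adjusted p = 0.0875 and 0.123). Of 21 fibroblast and immune markers, 6 were read often enough to be tested, 2 rose and none fell, against 2 and 1 over the list alone (camera adjusted p = 0.859). COL1A1 went from 12.5 ± 1.10 to 21.2 ± 3.22 CPM and the endothelial cadherin gene CDH5 from 0.497 ± 0.071 to 1.55 ± 0.275 CPM (SD, n = 2 each). COL1A1 holds TCAAGAT or CAAGATA in its coding sequence. CDH5 lost its call without NSUN7 siRNA library 1 (edgeR adjusted p = 0.0586) and without either control siRNA library (edgeR adjusted p = 0.155 and 0.237), and COL1A1 without control siRNA library 2 (edgeR adjusted p = 0.121) and without NSUN7 siRNA library 2 (edgeR adjusted p = 0.0634). Over all 34 lists, camera with the preset correlation called 3, 1 upward and 2 downward. With an estimated correlation none was called, the smallest adjusted p being 0.999, and 7 lists had an unadjusted preset-correlation p under 0.05. With fry none moved on balance one way (smallest adjusted p = 0.298), while 25 changed in either direction. The median and the mean of the log2 fold changes differed in sign for the basal, mesenchymal, p53, RAS and MAPK, hypoxia and RNA interference lists. The camera and fry directions differed for the mesenchymal, TGF-beta, NOTCH and RAS and MAPK lists.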

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

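Of the alternatives here, robust dispersions, the newer quasi-likelihood of edgeR, the leaving out of genes with the 3′ UTR heptamers and the count of coding NSUN7 transcripts were chosen after the results had been seen. With 2 libraries per group, a fit without 1 library leaves a group with a lone library that is assumed to vary like the other group, and low reads limit genes such as PGR, GREB1 and BCL2. The 756 calls with edgeR became 785 with DESeq2 size factors, 860 with the 50-read filter, 557 with counts rebuilt from TPM, 1119 in protein-coding genes only, 916 with robust dispersions and 780 with the newer quasi-likelihood. They became 280 without a filter, 1580 with DESeq2, 272 with limma-trend on log2(TPM + 1), 451 on log2(TPM + 0.1), 347 without heptamer genes (268 of the 756 calls were left out with their genes), and 380 to 1761 when 1 library was left out. Of these, 183, 793, 126, 189 and 222 rose and 97, 787, 146, 262 and 125 fell, and 246 to 888 rose and 134 to 873 fell when 1 library was left out, while 512 fell in protein-coding genes only. Calls of at least 1.5-fold went from 598 to 280 without a filter, 245 and 369 with limma-trend, 309 without heptamer genes and 380 to 1062 with 1 library left out. Calls shared with the edgeR fit never changed direction. Apart from the genes left out, the cause was not tested.

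The replicate numbers are not tied to a shared batch by the labels, and the deviations of libraries with the same number had a correlation of 0.206. With the number as a block there were 3570 calls (1834 rose, 1736 fell, 1346 of at least 1.5-fold), and NSUN7 passed with a log2 fold change of −0.78 (edgeR adjusted p = 0.00168, against 0.0942 in the edgeR fit without a block and 0.0565 to 0.345 for its summed reads under the other alternatives that include the gene). The block takes up part of the 2 residual degrees of freedom that the fit without it had. With nearly the same log2 fold changes (TIMP3 1.946 against 1.953, CAB39L −1.253 against −1.249), p-values became smaller by many orders of magnitude. The spread between libraries is thus poorly measured with the block. Its larger number of calls and the pass of NSUN7 are therefore not taken as evidence of a change. Counted from coding transcripts only, NSUN7 had a log2 fold change of 0.0619. The 3 lists called by camera became 4 without heptamer genes, 0 with an estimated correlation, 0 with fry, 1 with the 50-read filter, 2 with the block, where DNA repair was lost (camera adjusted p = 0.0557), and 1 to 8 with 1 library left out. With 1 library left out, PGR ranged from −3.28 to 0.0432, GREB1 from −1.42 to 0.27 and BCL2 from −0.13 to 0.24, and BCL2 was −0.0372 and −0.19 with limma-trend and −0.27 with counts rebuilt from TPM. The cause was not tested. Over the named genes and all alternatives, 2029 results stayed the same, 205 were stronger, 198 weaker and 7 reversed.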

Other observations

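The genes in these paragraphs, the heptamer search, its random sets of genes and the tests of base composition and of retained introns were chosen after the results had been seen. Among 7941 protein-coding genes without any of the 3 heptamers in the 3′ UTR or coding sequence, 120 rose and 99 fell. Among those with a mean log2 CPM of at least 3 and no overlap between the groups, the largest rises beside ATP6AP1, IQSEC1 and KIF12 were in the scramblase family gene ANO10 (1.68 ± 0.17), the endocytic recycling gene EHD3 (1.30 ± 0.12), SAR1B, a GTPase of vesicle budding from the endoplasmic reticulum (1.27 ± 0.11), the fatty acid elongase gene ELOVL7 (1.26 ± 0.14), the reductase gene CYB5R4 (1.18 ± 0.18), the citric acid cycle gene IDH3A (1.15 ± 0.14) and the chromatin organizer gene SATB2 (1.14 ± 0.15, log2 fold changes ± SE). With the same limits, the largest falls beside CLCN4, TNFSF15, AJUBA, CAB39L, SLC7A11 and CYP1A1 were in the kinesin gene KIFC3 (−1.14 ± 0.15), the polycomb gene SCML2 (−1.10 ± 0.15), CCDC170, a neighbour of ESR1 (−1.02 ± 0.10), and the sodium channel gene SCNN1G (−1.02 ± 0.22).

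Of the genes called that do not code for protein, 26 rose and 29 fell. BCYRN1, the BC200 RNA, rose from 49.6 ± 7.69 to 87.0 ± 20.6 CPM (SD, n = 2 each), and EBLN3P, ZNF37BP and LINC00886 rose by 0.71 ± 0.13, 1.05 ± 0.23 and 1.02 ± 0.22 on the log2 scale (SE). LINC02875 fell from 19.5 ± 2.18 to 9.15 ± 0.076 CPM (SD, n = 2 each), and MIR3648-1, PLEKHA8P1 and MIR1915HG fell by 2.34, 1.31 and 0.91 on the log2 scale.

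The rise of genes with GCAGTAC in the 3′ UTR may reflect repression by the control siRNA in the control libraries, through pairing of its seed. In the scan GCAGTAC had the largest z (25.2) of 16249 heptamers. With it in the 3′ UTR only, the mean residual was 0.205 higher (95% interval 0.151 to 0.259) than in the coding sequence only. This explanation had predicted such a difference, but GCAGTAC had been chosen for its 3′ UTR shift in these genes. The 1201 genes with it in the coding sequence only rose too (mean residual 0.152, 95% interval 0.133 to 0.172). The rise was thus not confined to genes with it in the 3′ UTR. Scanned in each of 2 random sets of 5193 genes, GCAGTAC came first both times, and in the genes outside the set the difference was 0.238 (95% interval 0.162 to 0.318) and 0.171 (95% interval 0.0973 to 0.245). Both sets come from the same 4 libraries, and the intervals carry no spread between libraries. Its shift was 0.398, and its 602 anagrams gave −0.101 to 0.175. As GCAGTAC was chosen for its z in these same genes, this alone cannot exclude composition of the 3′ UTR. In the genes outside each set, where it had not been chosen, the mean residual with it in the 3′ UTR only was 0.3876 and 0.3265. Both values lie above the highest anagram shift over all genes (0.175). This argues against composition of the 3′ UTR as the cause for GCAGTAC, within these 4 libraries. A single library out of line was excluded, since the lowest of 4 single-library shifts was 0.35. An effect of NSUN7 loss on these genes was not tested, because no library came from untransfected cells, and the siRNA sequences are not given.

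The fall of genes with TCAAGAT or CAAGATA may in the same way reflect the seed of the NSUN7 siRNA. The mean residual was −0.0654 (95% interval −0.0876 to −0.0414) for genes with these in the 3′ UTR only. With these in the coding sequence only it was −0.0121 (95% interval −0.027 to 0.0029), so no shift was detected there. TCAAGATA, which holds both heptamers, did go with a shift in the coding sequence only (−0.0682, 95% interval −0.102 to −0.0331). The explanation was taken to predict TCAAGATA in NSUN7, although a match to 1 of the heptamers alone would not require it. It lies in 3 NSUN7 transcripts, but 6.39% of 3256 genes with transcripts of similar length hold it too. NSUN7-201 and NSUN7-202 each hold TCAAGAT 2 times and CAAGATA 3 times. The same site lies in the retained-intron transcript NSUN7-206, which had 2.44 and 2.87 CPM in the controls and 0 and 1.11 CPM in the NSUN7 siRNA libraries, and in the coding sequence of NSUN7-201 and NSUN7-202, while the protein-coding transcripts together did not fall (ratio 1.05), so the explanation stays open. CAAGATA had a shift of −0.095 (95% interval −0.122 to −0.068), and its anagrams were no lower than −0.0374. The shift of TCAAGAT, −0.089 (95% interval −0.116 to −0.0619), overlaps the lowest of its 419 anagrams (−0.087). Both heptamers were chosen for the lowest z in these same genes and were not tried in other genes. Composition of the 3′ UTR was therefore not excluded for either. A loss of NSUN7 as the cause of these falls was not tested.

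The fall of NSUN7 reads lay in a retained-intron transcript, for which less unspliced RNA in the NSUN7 siRNA libraries could account. Their mean share of reads on retained-intron transcripts was 1.165 times that of the controls, but this ratio rests on NSUN7 siRNA library 2 (4.24%). NSUN7 siRNA library 1 (3.18%), where NSUN7-206 had 0 reads, lay between the controls (3.28% and 3.09%). A lower share in both NSUN7 siRNA libraries was not seen, which argues against this explanation without excluding it. A mere shift of reads between NSUN7 transcripts would leave the summed reads of the gene unchanged. The upper bound of the 95% interval of the summed log2 fold change was −0.274, which argues against such a shift as the whole cause. This does not exclude it, because the interval was known beforehand and the summed fall did not pass over all genes (edgeR adjusted p = 0.0942). A shift of part of the reads stays possible. Whether the siRNA lowered the NSUN7 protein was not tested. The reads that the quantifier assigned to coding transcripts give no sign of it, but their division from the other transcripts is uncertain.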
